A study of Mus musculus with 8 samples.

How the data were processed

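Single muscle fibers of the extensor digitorum longus, a fast muscle of the hind leg, were profiled in wild-type mice at 4 ages. The labels give 2 biological replicates each at postnatal day 3 (P3), at postnatal day 7 (P7), in adults of 3 to 4 months and in aged mice of 24 to 25 months, with 8 arrays in all. Each sample is described as fibers of a pup or of a mouse, but the source of the pup samples is given as pups, so pooling of animals was not ruled out. Per the labels' protocols, muscles were digested with collagenase for 90 minutes, the fibers were washed to remove other cells, and RNA was extracted with Trizol. Per the labels' protocols, 1 ng of total RNA per array was amplified with a low-input kit and hybridised to a whole-transcript mouse gene array.

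The deposited values are intensities that, per the submitters' processing notes, the authors obtained with RMA, which corrects background, normalises quantiles between arrays and summarises probes into probe sets. Neither the software version nor a step back from the log2 scale is stated. The deposited intensities ran from 3.72 to 24410 on a linear scale, whereas log2 values had been assumed before the data were examined, so log2 was taken of every value. The table held 34760 probe sets, of which 21640 named exactly 1 gene symbol, 1321 named several and 11799 named none. Probe sets with several symbols or none were left out. The gene identifiers of 21553 of the single symbols matched the reference table, and the other 87 kept the symbol that was deposited.

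A probe set was kept when it lay above the array's median over all probe sets in at least 2 arrays, which 13176 did. Where a gene had several kept probe sets (661 genes), the one with the highest mean over the arrays stood for it. This left 12029 genes. No array was left out. For arrays the number of arrays limits the precision, here 2 per group with 4 residual degrees of freedom and a median prior of 3.34 degrees of freedom.

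Genes were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per age group and an empirical Bayes prior that followed a mean-variance trend. The comparisons were P7 against P3, Adult against P7, Adult against P3 and Aged against Adult, each tested two-sided with limma's moderated statistic, and an F test asked whether a gene differed among the 4 ages. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, and the threshold was an adjusted p under 0.05. Errors given with log2 differences are the standard errors of that fit. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

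For groups of genes, 34 lists were fixed, and the 31 with at least 5 tested genes were tested with limma's camera at its preset correlation between genes of 0.01, which asks whether a list moves more than the other genes. The same lists were tested with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in 1 direction. With the estimated correlation p also rose for lists whose estimate lay below 0.01, such as the embryonic and neonatal sarcomere (0.0055). A call lost there is therefore not by itself a sign of correlated genes. Some lists share members. List p-values were adjusted over the lists within a comparison.

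The comparisons, tests, lists, thresholds and the rule for named genes were chosen before the data were examined, as were all alternatives except 3. Those 3, a crossed pairing of the Adult and Aged replicates, a pairing of P3 and P7 by replicate number and the share of X-linked genes without each Adult array, were chosen after the data had been seen. By the rule, each comparison names the 8 genes with the largest rise and the 8 with the largest fall among those that passed and whose groups did not overlap. Symbols of set patterns for predicted genes, non-coding RNAs and clones, olfactory and vomeronasal receptors and immune receptor segments were left out of that choice. The patterns did not cover Vaultrc5 or AW551984, which therefore stayed in. Where fewer passed, up to 3 genes per direction with the largest moderated statistic are given as values that did not pass. The rule adds up to 4 members with the smallest p of each list described and 16 fixed genes, of which H19 and Cdkn1a were not among the genes tested.

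The fit was tested on simulated data with the same design, in 20 draws with 200 changed genes of the 12029. A log2 change of 1 was recovered for 4.10% to 5.37% of the changed genes in the 4 comparisons, a change of 2 for 62.1% to 63.6% and a change of 3 for 87.0% to 89.2%. The share of false calls among all calls was 4.77% to 5.11%. All groups were drawn with the same spread. In the data the spread differed between groups, with array weights, which fall as spread grows, of 0.30 in Adult and 3.34 in Aged. The rates of recovery and of false calls therefore need not hold for these data. A list shifted by 1 was called in 20 of 20 draws in every comparison, and at most 2 of 380 unchanged lists were called. The simulated genes were drawn independently of each other. In the data the estimated correlation within a list reached 0.84 (fibroblast), so the rate of false list calls does not carry over to such lists.

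Alternatives changed the scaling between arrays (equal medians, cyclic loess, equal means of housekeeping genes), the filter on dim probe sets, the treatment of several probe sets per gene, the prior, array weights, the arrays in the fit, a block for the replicate numbers, and a fold threshold of 2. Each of the 8 arrays was also left out in turn. Where that left a group with 1 array, its spread was taken to be that of the other groups. No group held 3 or more arrays, so regroupings of the samples were not counted.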

Results

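The 8 arrays measured transcript levels in fibers of the extensor digitorum longus from mouse pups at P3 and P7, from adults and from aged mice, with 2 biological replicates per age. All differences below are log2 differences ± SE from a fit to all 8 arrays, with n = 2 per group. Each gene's error pools the spread of all age groups, and the median error was 0.29 in every comparison. The spread was not equal, with array weights of 0.30 in Adult and 3.34 in Aged. Errors and p-values of the comparisons with Adult may therefore be too small for the spread of the Adult arrays. The median intensity of an array lay between 64.8 and 71.9. Replicates correlated across all probe sets with r = 0.976 at P3, 0.982 at P7, 0.938 in Adult and 0.989 in Aged. Adult replicate 1 stood apart, with correlations of 0.933 to 0.953 to the other 7 arrays, while Adult replicate 2 correlated with the Aged arrays at 0.985 and 0.984. Genes are not independent replicates, so these coefficients carry no p-value.

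Adult replicate 1 also held the highest levels of fibroblast, endothelial, smooth muscle and tendon cell markers of all arrays. Its satellite cell markers (8.17) and Schwann cell markers (8.41) lay above the other mature arrays (at most 7.20 and 7.33) but not above all pup arrays. Its fibroblast markers averaged 10.28 log2 intensity units against 7.19 in Adult replicate 2, 7.07 and 7.67 in the Aged arrays, 8.48 and 8.81 at P3 and 9.78 and 9.94 at P7. Endothelial markers averaged 10.42 in Adult replicate 1 and 8.37 in Adult replicate 2. Smooth muscle markers averaged 10.07 and 7.79, and tendon cell markers 10.68 and 7.06. Imprinted growth genes, which are high in both pup ages, averaged 8.10 in Adult replicate 1 and 7.78 in Adult replicate 2. Only 4 macrophage and leukocyte markers, 1 erythroid marker and 2 adipocyte markers passed the filter, so these 3 lists were not tested.

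**Figure D1:**
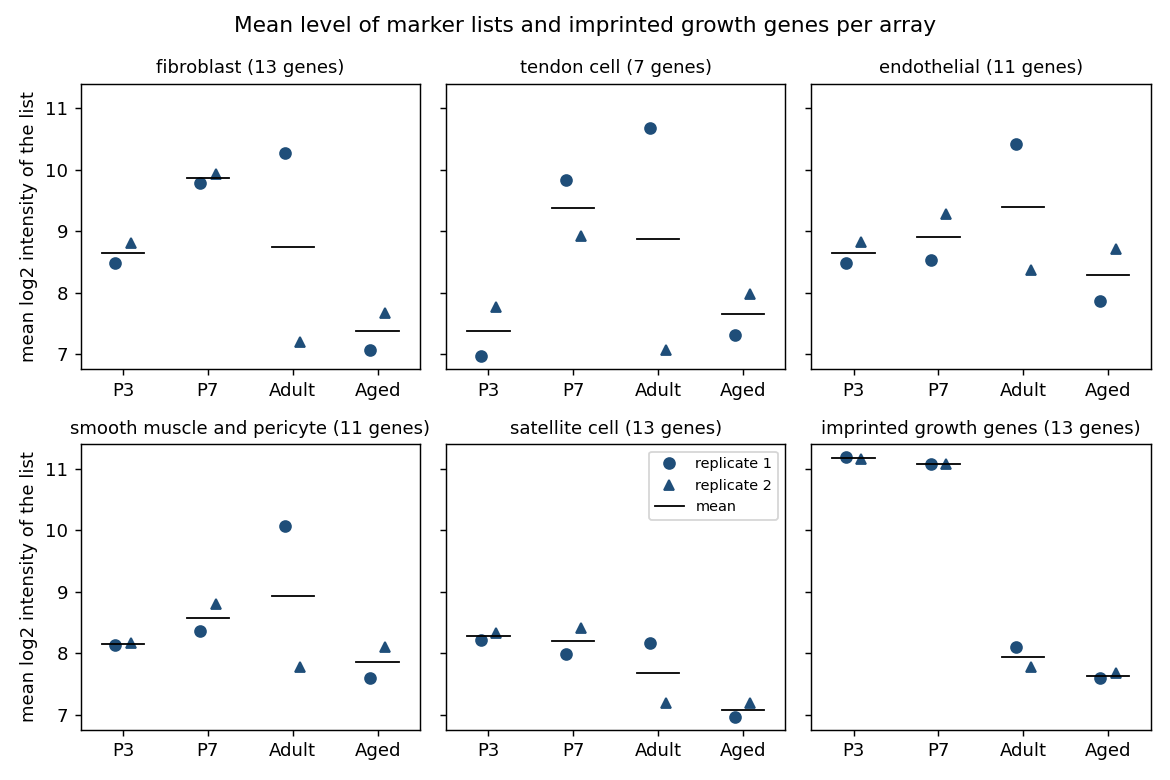
Mean log2 intensity (vertical axis) of 5 lists of cell markers and of the imprinted growth genes in each of the 8 arrays, by age (horizontal axis), with 1 symbol per replicate and a line at the group mean. The fibroblast mean is 10.28 in Adult replicate 1 and 7.19 in Adult replicate 2, and the imprinted growth genes lie between 7.60 and 8.10 in the 4 mature arrays and above 11 in the 4 pup arrays.

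The comparison of P7 with P3 asked what changes in fibers during the first week after birth. No gene passed the test. Lists of contractile and energy genes of fast fibers were called upward at the preset correlation, and no list was with an estimated correlation (adjusted p = 0.352 for the fast sarcomere, 0.468 for glycolysis and glycogen). Myh4, the myosin heavy chain of the fastest fibers, was higher at P7 by 1.79 ± 0.17 (adjusted p = 0.133), from 11.55 ± 0.18 (SD) to 13.35 ± 0.24 (SD). The calcium buffer Pvalb was higher by 1.22 ± 0.16 and the fast myosin-binding protein Mybpc2 by 1.36 ± 0.23. The myosins Myh1 (1.56 ± 0.39) and Myh2 (1.23 ± 0.43) of the other fast fiber types were also higher, and Myh3 (-0.42 ± 0.49), Myh8 (-0.32 ± 0.47) and Myh7 (-0.11 ± 0.41) differed by less than their errors. The errors in this comparison hold the spread of all 4 age groups, not that of the pup arrays alone. For Myh8 the Adult arrays differed widely, as Adult against P7 was -6.03 without Adult replicate 1 and -4.50 without Adult replicate 2.

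All 13 fast sarcomere genes were higher at P7, 0 passed over all genes and 6 rose when adjusted over the list alone. Camera called the fast sarcomere upward (adjusted p = 2.25e-07, median 0.21, adjusted p = 0.352 with an estimated correlation). Of the 16 genes of glycolysis and glycogen, 15 were higher, among them Gpd1 (1.04 ± 0.19), which links glycolysis to glycerol phosphate, and Phkg1 (0.96 ± 0.25), a subunit of the kinase that starts glycogen breakdown. None passed over all genes and 4 rose when adjusted over the list alone. Camera called the glycolysis list upward (adjusted p = 1.67e-06, adjusted p = 0.468 with an estimated correlation). The 17 genes of excitation-contraction coupling, which release calcium on a nerve impulse, were called upward with 15 higher, such as the calcium release channel Ryr1 at 0.65 ± 0.17 (adjusted p = 4.02e-04, adjusted p = 0.631 with an estimated correlation). The denervation response genes were called downward with 12 of 14 lower, including the fetal acetylcholine receptor subunit Chrng at -1.18 ± 0.45 and the calcium pump regulator Sln at -1.18 ± 0.34 (adjusted p = 3.75e-04, adjusted p = 0.631 with an estimated correlation). Cytosolic ribosome genes were called downward with 22 of 23 lower and a median of -0.26 (adjusted p = 1.61e-04, adjusted p = 0.631 with an estimated correlation), which was -0.090 without P3 replicate 2 (adjusted p = 0.0438). In each of these 3 lists 0 members passed, over all genes or adjusted over the list alone.

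Markers of connective tissue were higher at P7 as well. Fibroblast genes were called upward with 12 of 13 higher, for example the collagen genes Col1a1 at 2.62 ± 1.22 and Col1a2 at 2.95 ± 1.39 (adjusted p = 0.0024, adjusted p = 0.635 with an estimated correlation). Tendon cell genes were called upward with 6 of 7 higher, for example Fmod at 3.93 ± 1.43 (adjusted p = 0.0373, adjusted p = 0.631 with an estimated correlation). Immediate early genes (13 of 15 higher) were called upward with an adjusted p of 0.0095, which was 0.631 as an adjusted p with an estimated correlation. Circadian clock genes (13 of 15 higher) were called upward with an adjusted p of 0.0057, which was 0.468 as an adjusted p with an estimated correlation. Other niche ligands, secreted or surface signals that act on neighboring stem cells, had 16 of 21 higher (adjusted p = 0.0472, adjusted p = 0.502 with an estimated correlation). In these 5 lists 0 members passed, over all genes or adjusted over the list alone. Equal housekeeping means ended the call of tendon cell genes (adjusted p = 0.0517). Without P3 replicate 1 the adjusted p was 0.0895 for fibroblast genes, 0.353 for tendon cell genes, 0.600 for immediate early genes, 0.138 for the circadian clock and 0.138 for other niche ligands. Without P7 replicate 1 it was 0.287 for tendon cell genes, 0.843 for immediate early genes, 0.0786 for the circadian clock and 0.163 for other niche ligands, which also lost the call without P3 replicate 2 (0.105) and without P7 replicate 2 (0.0746). In the median, mean and test, signs differed for the lists of the neuromuscular junction, myogenic regulators, the unfolded protein response and heat shock, none of which was called.

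By limma 0 genes differed between P7 and P3 at the threshold, 651 had an unadjusted p under 0.05 (483 higher, 168 lower), and the lowest adjusted p was 0.133. Among the genes with the largest moderated statistics were Sorl1 (2.10 ± 0.26), a sorting receptor, and Acan (1.70 ± 0.22), a cartilage proteoglycan, both with an adjusted p of 0.277, and Mettl21e (-1.94 ± 0.28, adjusted p = 0.325) and Kcnf1 (-2.06 ± 0.32, adjusted p = 0.358). Rin1 was at -1.25 ± 0.23 (adjusted p = 0.530). Of the lists, 8 were called upward and 2 downward of 31 by camera, 0 with an estimated correlation, and 1 by fry, the fast sarcomere (adjusted p = 0.0473). Without Adult replicate 1, which enters this comparison through the shared spread, 19 genes passed, and without Adult replicate 2 22 passed. A fit to the 4 arrays of P3 and P7 alone gave 49 genes (47 higher, 2 lower). Pairing these 4 arrays by replicate number, chosen after the data had been seen, gave 330 genes (283 higher, 47 lower).

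The comparison of Adult with P7 asked how neonatal fibers mature into adult ones. The neonatal myosin Myh8 fell by 5.26 ± 0.47 on the log2 scale (adjusted p = 0.003) and the embryonic myosin Myh3 fell by 4.41 ± 0.49 (adjusted p = 0.0066). Genes of fetal growth fell as well, with the imprinted surface protein Dlk1 at -5.98 ± 0.28 (adjusted p = 3.79e-04) and the growth factor Igf2 at -4.62 ± 0.33 (adjusted p = 0.0014). Among the genes that rose were Aldh1a1, a retinaldehyde dehydrogenase (3.58 ± 0.26, adjusted p = 0.0014), Ces1d, a carboxylesterase (3.35 ± 0.21, adjusted p = 0.0011), and Cd55, which shields cells from complement (2.66 ± 0.22, adjusted p = 0.0027). Without either P7 replicate 1 or P7 replicate 2 Myh3 did not pass.

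**Figure D2:**
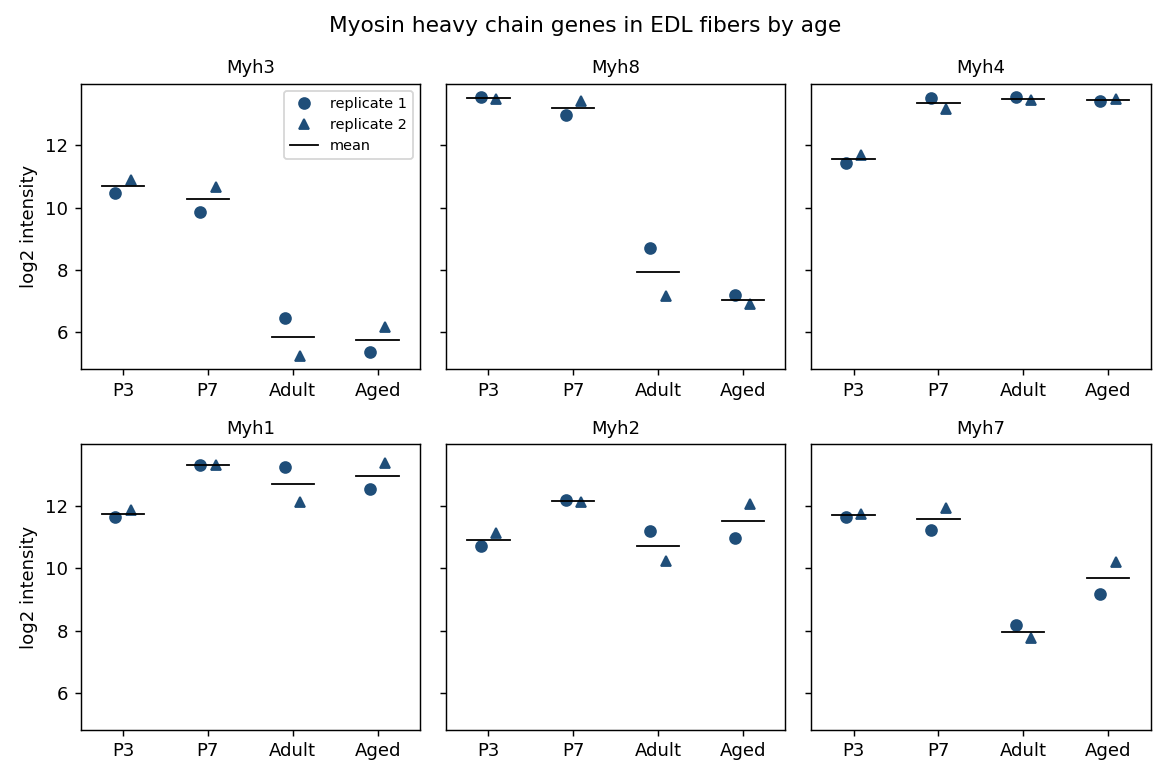
Log2 intensity (vertical axis) of 6 myosin heavy chain genes in each of the 8 arrays by age (horizontal axis), with 1 symbol per replicate and a line at the group mean. Myh8 lay between 12.99 and 13.56 in the 4 pup arrays and between 6.91 and 8.71 in the 4 mature arrays.

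Sarcomere genes divided by fiber program. Of 8 embryonic and neonatal sarcomere genes 5 fell over all genes and 6 when adjusted over the list alone, among them the cardiac actin Actc1 (-1.37 ± 0.16) and the embryonic light chain Myl4 (-1.39 ± 0.25). Camera called the embryonic list downward (adjusted p = 2.65e-05, adjusted p = 0.0951 with an estimated correlation). Of 12 slow sarcomere genes 8 fell and 10 when adjusted over the list alone, among them the slow myosin Myh7 (-3.61 ± 0.41), the calcium-binding protein Casq2 (-4.37 ± 0.54), the slow troponin Tnni1 (-2.88 ± 0.37) and Myoz2 (-2.78 ± 0.37). The slow list was called downward (adjusted p = 2.35e-09, median -2.71, adjusted p = 0.295 with an estimated correlation). Of 13 fast sarcomere genes 1 rose, the myosin light chain kinase Mylk2 (1.08 ± 0.21, adjusted p = 0.0407), also adjusted over the list alone. Myh4 differed by 0.15 ± 0.17, Myh1 by -0.62 ± 0.39 and Myh2 by -1.45 ± 0.43 (adjusted p = 0.131), and the list was not called (adjusted p = 0.328, median 0.08, mean below 0). Calls of Myh7, Actc1, Myl4, Casq2, Tnni1, Myoz2 and Mylk2 were lost without P7 replicate 1 and without P7 replicate 2, and those of Myl4 and Mylk2 also without any one of the P3 or Aged arrays. Equal housekeeping means ended the call of Myl4 too.

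**Figure D3:**
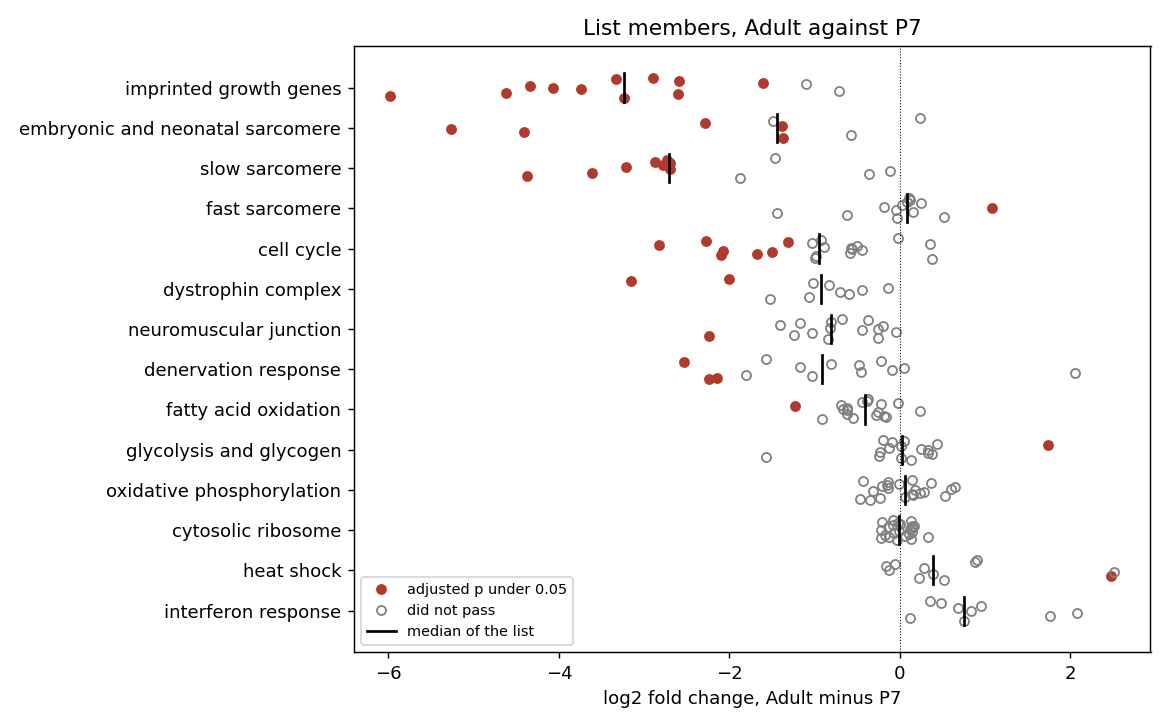
Log2 fold change of Adult against P7 (horizontal axis) for each tested member of 14 gene lists (vertical axis), with filled points for members with an adjusted p under 0.05 and a bar at the median of each list. The medians are -3.23 for imprinted growth genes, -2.71 for slow sarcomere genes and 0.08 for fast sarcomere genes.

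Growth, proliferation and fusion genes were lower in Adult. Of 13 imprinted growth genes 11 fell over all genes and 13 when adjusted over the list alone, with Meg3, a long non-coding RNA, at -3.74 ± 0.24 and the growth factor receptor adaptor Grb10 at -2.61 ± 0.25. This list was called with the preset correlation (adjusted p = 8.61e-16) and with the estimated correlation (adjusted p = 0.0266). Of 20 cell cycle genes 7 fell and 12 when adjusted over the list alone, including the proliferation antigen Mki67 (-2.82 ± 0.23), the topoisomerase Top2a (-2.27 ± 0.24), the kinase Cdk1 (-1.50 ± 0.21) and the cyclin Ccna2 (-2.10 ± 0.32). Camera called the cell cycle list downward (adjusted p = 1.16e-07, adjusted p = 0.0951 with an estimated correlation). Of 12 myogenic regulators and fusion genes 1 fell, the membrane fusion protein Mymk (-4.07 ± 0.29, adjusted p = 0.0014), also adjusted over the list alone. Camera called the myogenic list downward (adjusted p = 0.0453, adjusted p = 0.295 with an estimated correlation). That list call was lost without P7 replicate 1 (adjusted p = 0.066), P7 replicate 2 (0.0568) or Adult replicate 1 (0.360). Grb10, Cdk1 and Ccna2 did not pass without P7 replicate 1 or without P7 replicate 2, Cdk1 also not without Aged replicate 2, and Top2a not without P7 replicate 1.

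Genes at the contact with the nerve and the membrane were lower. All 15 neuromuscular junction genes were lower, of which 1 fell over all genes and 5 when adjusted over the list alone. Camera called the junction list downward (adjusted p = 0.0021, adjusted p = 0.266 with an estimated correlation). The one that fell was the acetylcholine receptor subunit Chrna1 (-2.24 ± 0.27, adjusted p = 0.0076), while the fetal subunit Chrng was at -1.80 ± 0.45 (adjusted p = 0.0872) and the adult subunit Chrne at -0.05 ± 0.31. Of 14 denervation response genes 3 fell over all genes and 6 when adjusted over the list alone. The 3 were Chrna1, the adhesion molecule Ncam1 (-2.53 ± 0.30) and the receptor subunit Chrna9 (-2.15 ± 0.27). Camera called the denervation list downward (adjusted p = 0.0032, adjusted p = 0.577 with an estimated correlation). Of 10 dystrophin complex genes, which anchor the membrane, all were lower, 2 fell over all genes and 6 when adjusted over the list alone. Those 2 were Sntb1 (-3.16 ± 0.42) and Sspn (-2.01 ± 0.32). Camera called the dystrophin list downward (adjusted p = 3.93e-04, adjusted p = 0.119 with an estimated correlation). With Adult replicate 1 left out, the denervation list had a median of 0.02 (adjusted p = 0.875). Chrna1, Ncam1, Sntb1 and Sspn did not pass without P7 replicate 1 or without P7 replicate 2, Sspn also not without Aged replicate 1 or Aged replicate 2, and Chrna9 not without P7 replicate 2. Sspn did not pass under equal housekeeping means either.

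Of 18 fatty acid oxidation genes 17 were lower, and Hadh, a beta-oxidation enzyme, fell (-1.23 ± 0.17), as did 4 genes when adjusted over the list alone. Camera called the oxidation list downward (adjusted p = 0.0032, adjusted p = 0.560 with an estimated correlation). The glycogen kinase subunit Phka1 rose (1.74 ± 0.21, adjusted p = 0.0081), the only one of 16 glycolysis and glycogen genes that did over all genes or adjusted over the list alone. The 21 oxidative phosphorylation genes had a median of 0.06 and 0 passed. Of 11 heat shock genes 1 rose, the chaperone partner Dnajb1 (2.48 ± 0.33, adjusted p = 0.0116), and 3 when adjusted over the list alone. Camera called the heat shock list upward (adjusted p = 0.0032, adjusted p = 0.390 with an estimated correlation). All 9 interferon response genes were higher in Adult, such as Ifit1 (1.76 ± 0.47) and Ifit3 (2.08 ± 0.65), and 0 passed either way. Camera called the interferon list upward (adjusted p = 0.0032, adjusted p = 0.585 with an estimated correlation). Interferon response genes averaged 8.31 in Adult replicate 1 and 7.03 in Adult replicate 2, and without Adult replicate 1 the list lost its call (adjusted p = 0.451, median 0.08), as did fatty acid oxidation (adjusted p = 0.0714). Without Adult replicate 2 the heat shock list lost its call (adjusted p = 0.154). Hadh, Phka1 and Dnajb1 did not pass without P7 replicate 1 or without P7 replicate 2, and Hadh also not without Aged replicate 2 or under equal housekeeping means.

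Satellite cell markers were not called between Adult and P7 (median -0.66, adjusted p = 0.0871), and the stem cell factor Pax7 was at -0.45 ± 0.32. The satellite list was called downward under cyclic loess (adjusted p = 0.0328), equal housekeeping means (0.0476), without Adult replicate 1 (0.0016) and without P7 replicate 1 (0.0267), while its median was -0.11 without Adult replicate 2 (0.899) and its adjusted p = 0.623 with an estimated correlation. Fibroblast markers were not called (median -0.90, adjusted p = 0.0871), but were under equal array medians (0.0263) and equal housekeeping means (0.0389). Their direction hung on the Adult array, with a median of -2.55 without Adult replicate 1 (adjusted p = 3.93e-09) and 0.77 without Adult replicate 2 (adjusted p = 0.131). Basement membrane genes were called downward with 16 of 17 lower and 0 that passed either way (adjusted p = 0.0013, adjusted p = 0.609 with an estimated correlation), a call lost without Adult replicate 2 (adjusted p = 0.573). Of 21 other niche ligands 1 fell, the Wnt signal enhancer Rspo3 (-1.89 ± 0.35, adjusted p = 0.0354), and 2 fell when adjusted over the list alone, while the Notch ligands Dll4 (0.10 ± 0.79) and Jag2 (-0.33 ± 0.34) did not pass. None of 9 Wnt ligands passed, with Wnt4 at -0.82 ± 0.34 (adjusted p = 0.242). Of 11 senescence genes 1 rose, the metalloproteinase Mmp3 (1.79 ± 0.37, adjusted p = 0.0475), also adjusted over the list alone, and the cell cycle inhibitor Cdkn2a was at 0.56 ± 0.18 (adjusted p = 0.163). Mmp3 did not pass without any one of the P3, P7 or Aged arrays, and Rspo3 not without any one of these 6 except P7 replicate 1. Mmp3 also lost its call under cyclic loess and Rspo3 under equal housekeeping means.

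Of 12029 genes 431 changed between P7 and Adult, 129 higher and 302 lower, and 424 of them by at least 2-fold. The excess of falls depended on the scaling, with 137 higher and 153 lower under equal housekeeping means and 165 and 215 under equal array medians. Equal housekeeping means shifted Adult replicate 1 by 0.371 and Adult replicate 2 by -0.100. A fit to the compared groups alone gave 45 genes and array weights gave 112. Other genes with large falls were Kcne1l, a potassium channel subunit (-6.32 ± 0.26), Atp1b4, a beta subunit relative of the sodium pump (-5.88 ± 0.34), AW551984 (-5.86 ± 0.55), Prr32 (-5.41 ± 0.31) and Fndc3c1 (-5.15 ± 0.32). Other genes with large rises were the carbonyl reductase Cbr2 (3.46 ± 0.68), the small non-coding vault RNA Vaultrc5 (3.30 ± 0.37), Tspan8 (3.02 ± 0.47), Lrrc30 (2.96 ± 0.22) and the mitochondrial sulfide oxidase Sqor (2.90 ± 0.30). Of the lists camera called 2 upward and 10 downward of 31, 1 with an estimated correlation, and fry called 8. The count was 1778 without Adult replicate 1 and 1892 without Adult replicate 2, and each of these sets held all 431 genes. It was 46 and 61 without P7 replicate 1 and 2, 247 and 243 without P3 replicate 1 and 2, and 149 and 147 without Aged replicate 1 and 2. Cbr2 did not pass without any one of the P3, P7 or Aged arrays, Tspan8 not without any one of the P3 or P7 arrays, and Vaultrc5, AW551984 and Sqor not without either P7 array. The rise of Cbr2 was 4.70 without Adult replicate 1 and 2.23 without Adult replicate 2.

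The comparison of Adult with P3 spanned the whole of postnatal maturation. Myh4 rose by 1.94 ± 0.17 (adjusted p = 0.0022) while Myh8 fell by 5.58 ± 0.47 (adjusted p = 0.0018), Myh3 fell by 4.83 ± 0.49 (adjusted p = 0.0037) and Myh7 fell by 3.73 ± 0.41 (adjusted p = 0.0044). The fetal receptor subunit Chrng fell by 2.99 ± 0.45 (adjusted p = 0.0131), a call lost without P3 replicate 2, and Chrne was at 0.96 ± 0.31 (adjusted p = 0.126). Igf2 fell by 4.63 ± 0.33 and all 13 imprinted growth genes fell, over all genes and adjusted over the list alone (camera adjusted p = 2.30e-16, adjusted p = 0.0248 with an estimated correlation). Aldh1a1 had the largest rise of the genes named, 5.06 ± 0.26 (adjusted p = 5.01e-04).

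Fast sarcomere genes were called upward between P3 and Adult, with 5 of 13 that rose over all genes and adjusted over the list alone, and 3 lower (adjusted p = 9.17e-05, adjusted p = 0.187 with an estimated correlation). Pvalb (1.47 ± 0.16) and Mybpc2 (1.87 ± 0.23) were among those that rose. Slow sarcomere genes were called downward with 8 of 12 that fell and 10 when adjusted over the list alone, a call with adjusted p = 5.48e-10 (adjusted p = 0.220 with an estimated correlation). They included Tnni1 (-3.46 ± 0.37), the light chain Myl2 (-3.52 ± 0.40) and the slow troponin Tnnc1 (-3.60 ± 0.41). Embryonic and neonatal sarcomere genes were called downward, 5 of 8 fell and 6 when adjusted over the list alone (adjusted p = 2.06e-05, adjusted p = 0.0914 with an estimated correlation). Of 20 cell cycle genes 9 fell and 12 when adjusted over the list alone, with Mki67 at -2.97 ± 0.23 (adjusted p = 7.71e-08 for the list, adjusted p = 0.0914 with an estimated correlation). Of 16 glycolysis and glycogen genes 4 rose and 1 fell, with 6 and 1 when adjusted over the list alone. Upward was also the call of camera (adjusted p = 1.02e-04, adjusted p = 0.260 with an estimated correlation). Among these Phka1 rose by 2.18 ± 0.21 and the glycolytic enzyme Pfkm by 0.81 ± 0.14, while Fbp2, which acts in the reverse direction, fell by 2.28 ± 0.47. Of 18 fatty acid oxidation genes 3 fell and 4 when adjusted over the list alone, with the dehydrogenase Acadl at -1.38 ± 0.22 (adjusted p = 3.77e-04 for the list, adjusted p = 0.336 with an estimated correlation). Of the genes named here, Pfkm and Fbp2 did not pass without any one of the P3, P7 or Aged arrays, and Acadl not without P3 replicate 1 or P3 replicate 2. Fbp2 was at -1.49 without Adult replicate 1 and at -3.07 without Adult replicate 2.

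Between P3 and Adult 5 of 14 denervation response genes fell, and 7 when adjusted over the list alone. Among them were Chrna9 (-3.25 ± 0.27), Ncam1 (-2.90 ± 0.30) and Sln (-2.75 ± 0.34). The list as a whole was called downward (adjusted p = 7.05e-05, adjusted p = 0.336 with an estimated correlation). The neuromuscular junction list was called downward with 1 of 15 that fell, Chrna1 (-2.48 ± 0.27), and 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0061, adjusted p = 0.220 with an estimated correlation). Dystrophin complex genes were called downward with 1 of 10 that fell, Sntb1 (-3.20 ± 0.42), and 2 when adjusted over the list alone (adjusted p = 0.0063, adjusted p = 0.195 with an estimated correlation). Immediate early genes were called upward with 1 of 15 that rose, the phosphatase Dusp1 (1.74 ± 0.28), and 6 when adjusted over the list alone (adjusted p = 9.14e-04, adjusted p = 0.360 with an estimated correlation). Circadian clock genes were called upward with 1 of 15 that rose, the clock repressor Ciart (1.38 ± 0.26), and 6 when adjusted over the list alone (adjusted p = 0.0011, adjusted p = 0.187 with an estimated correlation). Of 17 atrophy and autophagy genes 3 rose over all genes and adjusted over the list alone, including the ubiquitin ligase Fbxo32 (2.18 ± 0.39) (adjusted p = 0.0478 for the list, adjusted p = 0.389 with an estimated correlation). The atrophy call was lost without P3 replicate 2, Adult replicate 2, or any one of the P7 and Aged arrays, and in each of the 3 other scalings. Leaving out Adult replicate 1 gave the denervation list an adjusted p of 0.0555. Sln and Sntb1 did not pass without P3 replicate 1, Dusp1 not without P3 replicate 2, Ciart not without any one of the P3, P7 or Aged arrays, and Fbxo32 not without any one of these 6 except P3 replicate 2.

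Satellite cell markers were called downward between P3 and Adult, with 1 of 13 that fell, the myogenic factor Myf5 (-1.27 ± 0.28, adjusted p = 0.0466), and 2 when adjusted over the list alone (adjusted p = 0.0231, adjusted p = 0.404 with an estimated correlation). The list call was lost without P3 replicate 2 (adjusted p = 0.0907) or Adult replicate 2 (0.761), and Myf5 did not pass without any one of the P3, P7 or Aged arrays, nor under equal array medians or equal housekeeping means. Pax7 was at -0.97 ± 0.32 (adjusted p = 0.141). Myogenic regulators were called downward with 1 of 12 that fell, Mymk (-4.10 ± 0.29), also adjusted over the list alone (adjusted p = 0.0245, adjusted p = 0.220 with an estimated correlation). The myogenic call was lost without P3 replicate 2 (0.058) or Adult replicate 1 (0.0701). All 9 interferon response genes were higher, 0 rose over all genes and 2 when adjusted over the list alone (adjusted p = 5.35e-04, adjusted p = 0.389 with an estimated correlation). The interferon call was lost without Adult replicate 1 (0.0765). Heat shock genes were called upward with 2 of 11 that rose, Dnajb1 (3.01 ± 0.33) and the chaperone Hspa1a (3.72 ± 0.67), and 3 when adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.340 with an estimated correlation). The heat shock call was lost without P3 replicate 2 (0.0704) or Adult replicate 2 (0.428, median -0.12). Senescence genes were called upward with 1 of 11 that rose, Mmp3 (1.88 ± 0.37), also adjusted over the list alone (adjusted p = 0.043, adjusted p = 0.328 with an estimated correlation). The senescence call was lost without P3 replicate 1 (0.197), Adult replicate 1 (0.1002) or Adult replicate 2 (0.0913) and in each of the 3 other scalings. Basement membrane genes were called downward, with 17 of 17 lower and 0 that passed either way (adjusted p = 0.0134, adjusted p = 0.648 with an estimated correlation). Without Adult replicate 2 their median was 0.11, and without P3 replicate 2 the adjusted p was 0.0663. Of the unfolded protein response genes 2 of 15 fell, the asparagine synthetase Asns (-3.15 ± 0.62) and Trib3 (-2.02 ± 0.41). When adjusted over the list alone 1 rose and 2 fell, and the list was not called (adjusted p = 0.456). Hspa1a did not pass without P3 replicate 1, and Mmp3, Asns and Trib3 not without any one of the P3, P7 or Aged arrays.

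Signal genes toward the stem cell niche went in both directions between P3 and Adult. Of 21 other niche ligands the growth factor Egf rose (1.41 ± 0.23, adjusted p = 0.0171) and Rspo3 fell by 2.10 ± 0.35 (adjusted p = 0.0181), both also adjusted over the list alone, and the list was not called (adjusted p = 0.839). Neither passed without P3 replicate 1 or P3 replicate 2, and Egf also not without Aged replicate 1 or Aged replicate 2. Of 9 Wnt ligands 7 were lower and 0 passed, with Wnt4 at -1.12 ± 0.34 (adjusted p = 0.107), and under equal housekeeping means the median of this list turned from -0.11 to 0.055. Of the smooth muscle and pericyte markers the proteoglycan Cspg4 fell (-1.86 ± 0.34, adjusted p = 0.0236), a call lost under equal housekeeping means and without any one of the P3 or Aged arrays, and 1 rose and 1 fell when adjusted over the list alone.

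Between P3 and Adult 713 genes changed, 307 higher and 406 lower, 684 of them by at least 2-fold. Under equal housekeeping means 337 were higher and 240 lower, so the excess of falls turned into one of rises. That scaling shifted Adult replicate 1 by 0.371 and the other arrays by -0.148 to -0.009. The count was 60 in a fit to the compared groups alone and 138 with array weights. Large falls included AW551984 (-6.23 ± 0.55), Dlk1 (-6.04 ± 0.28), the kinase Nrk (-5.90 ± 0.35), Atp1b4 (-5.84 ± 0.34), Kcne1l (-5.80 ± 0.26), Prr32 (-5.71 ± 0.31) and Fndc3c1 (-5.40 ± 0.32). Large rises included Cbr2 (4.03 ± 0.68), the lubricating proteoglycan Prg4 (3.98 ± 0.81), Sqor (3.68 ± 0.30), Tmem140 (3.63 ± 0.57), the lipid transporter Abcb4 (3.50 ± 0.25) and Tspan8 (3.48 ± 0.47). The lists called by camera were 8 upward and 11 downward of 31, with 1 called with an estimated correlation and 14 by fry. Without P3 replicate 1 the count was 130 and without P3 replicate 2 it was 219. Without Adult replicate 1 it was 1711, which held 697 of the 713, and without Adult replicate 2 it was 2858, which held all 713. It was 424 and 422 without P7 replicate 1 and 2, and 335 and 333 without Aged replicate 1 and 2. Prg4 did not pass under equal housekeeping means or without any one of the P3, P7 or Aged arrays, Cbr2 not without any one of the P3 or P7 arrays, Tspan8 not without either P3 array, and Tmem140 not without P3 replicate 1. The rise of Prg4 was 2.59 without Adult replicate 1 and 5.37 without Adult replicate 2, and that of Cbr2 was 5.27 and 2.79.

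Of the genes called in these last 2 comparisons, 114 were higher in Adult than at both pup ages and 240 were lower than at both. Independent calls would share 3.29 and 10.2 genes, but the comparisons share the Adult arrays. Unchanged simulated groups with the same sharing gave 0.45 shared calls on average over 20 draws, both directions together. Those groups held no changed genes and so had few calls to share. The value therefore does not show how much of the overlap comes from the shared arrays. Across genes the correlation of the 2 sets of log2 differences was 0.86, and unchanged simulated groups gave 0.82. Genes were simulated independently of each other, so the value of 0.82 need not hold for these data. Across the 4 ages 712 genes differed by the F test. That count was 2432 with array weights, 228 and 299 without P3 replicate 1 and 2, 283 and 265 without P7 replicate 1 and 2, 2509 and 3842 without Adult replicate 1 and 2, and 183 and 191 without Aged replicate 1 and 2.

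The comparison of Aged with Adult asked what changes in fibers with age. No gene passed the test, and among the lists of fiber genes the slow sarcomere had the lowest p by camera at the preset correlation, though not by fry or with an estimated correlation. Myh7 was higher in Aged by 1.73 ± 0.41, the slow troponin Tnnc1 by 1.66 ± 0.41, and the light chains Myl2 by 1.60 ± 0.40 and Myl3 by 1.74 ± 0.45, each with an adjusted p of 0.783. Myh4 (-0.04 ± 0.17), Myh1 (0.26 ± 0.39) and Myh2 (0.80 ± 0.43) did not pass. The hormone-like peptide Ostn was higher by 3.23 ± 0.44 and Actc1 lower at -1.40 ± 0.16, both with an adjusted p of 0.321.

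Of 12 slow sarcomere genes 11 were higher in Aged, 0 passed over all genes and 6 rose when adjusted over the list alone. By camera the list was called upward (adjusted p = 1.97e-05, median 0.95, adjusted p = 0.513 with an estimated correlation). Without Adult replicate 1 the median was 1.41, and without Adult replicate 2 it was 0.77 and the call was lost (adjusted p = 0.238). It was 0.61 without Aged replicate 2 (adjusted p = 0.0048). Of 18 fatty acid oxidation genes 16 were higher and 0 passed either way. In a camera test the list was called upward (adjusted p = 4.96e-04, median 0.35, adjusted p = 0.513 with an estimated correlation), a call lost without Aged replicate 2 (adjusted p = 0.0544). The median of the oxidation list was 0.16 under cyclic loess and 0.13 under equal housekeeping means. Denervation response genes were called upward with 13 of 14 higher, for example the growth factor carrier Fgfbp1 at 2.56 ± 0.86, and 0 passed either way (adjusted p = 0.0021, adjusted p = 0.513 with an estimated correlation), but without Adult replicate 1 the median was 0.05 (adjusted p = 0.822). Glycolysis and glycogen genes were called upward with 15 of 16 higher and 0 passed either way (adjusted p = 0.0325, adjusted p = 0.513 with an estimated correlation), but under equal housekeeping means their median was -0.044. That call was lost without Adult replicate 1 (adjusted p = 0.740), Aged replicate 1 (0.0657) or Aged replicate 2 (0.0544).

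Marker lists of other cells were lower in Aged, beside the high levels of the same markers in Adult replicate 1. All 13 fibroblast genes were lower (median -1.24, adjusted p = 1.97e-05, adjusted p = 0.513 with an estimated correlation), and without Adult replicate 1 their median was 0.16. All 11 smooth muscle and pericyte genes were lower (median -1.42, adjusted p = 6.43e-05, adjusted p = 0.513 with an estimated correlation), and without Adult replicate 1 their median was 0.057. Of 17 basement membrane genes 15 were lower (median -0.81, adjusted p = 2.47e-04, adjusted p = 0.513 with an estimated correlation), and without Adult replicate 1 their median was 0.080. Of 11 endothelial genes 10 were lower (median -1.34, adjusted p = 7.69e-05, adjusted p = 0.513 with an estimated correlation), and without Adult replicate 1 their median was -0.07. Tendon cell genes (6 of 7 lower, adjusted p = 0.0325, adjusted p = 0.533 with an estimated correlation) had a median of 0.48 without Adult replicate 1, and lost the call without Aged replicate 1 (adjusted p = 0.0928). Interferon response genes (9 of 9 lower, adjusted p = 0.0325, adjusted p = 0.611 with an estimated correlation) had a median of 0.21 without Adult replicate 1, and lost the call without Aged replicate 1 (adjusted p = 0.633, median 0.02). In none of these 6 lists did a member pass, over all genes or adjusted over the list alone.

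Satellite cell markers were called downward in Aged with 10 of 13 lower (median -0.67, adjusted p = 0.0013, adjusted p = 0.513 with an estimated correlation), but Pax7 itself was at 0.16 ± 0.32, and without Adult replicate 1 the median was -0.14 (adjusted p = 0.584). Schwann cell and nerve markers were called downward with 5 of 5 lower (adjusted p = 0.0087, adjusted p = 0.513 with an estimated correlation), and without Adult replicate 1 the adjusted p was 0.740. Embryonic and neonatal sarcomere genes (6 of 8 lower) were called downward with an adjusted p of 0.0325, or an adjusted p = 0.513 with an estimated correlation, and in this list Actc1 fell when adjusted over the list alone. Imprinted growth genes (8 of 13 lower) were called downward with the same pair of values. The embryonic list lost its call without Adult replicate 1 (adjusted p = 0.155), Adult replicate 2 (0.199) or Aged replicate 2 (0.0648), and the imprinted list without Adult replicate 1 (0.381) or Adult replicate 2 (0.102). In the satellite, Schwann and imprinted lists 0 members passed, over all genes or adjusted over the list alone. Of 11 senescence genes 0 passed over all genes, 2 rose when adjusted over the list alone, the metalloproteinases Mmp3 (2.57 ± 0.37) and Mmp13 (1.66 ± 0.27), and the list was not called (adjusted p = 0.667). Cdkn2a was at -0.07 ± 0.18, the growth factor Igf1 at -1.99 ± 0.68 and Wnt4 at -0.03 ± 0.34, none past the threshold.

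By limma 0 genes differed between Aged and Adult, 415 had an unadjusted p under 0.05 (236 higher, 179 lower), and the lowest adjusted p was 0.321. Other genes with the largest moderated statistics were Prr32 (2.27 ± 0.31), Amy1, an amylase (1.32 ± 0.19), Casp12 (-1.44 ± 0.20) and the detoxifying enzyme Mgst1 (-1.73 ± 0.26), all with an adjusted p of 0.321. Of the lists 4 were called upward and 10 downward of 31 by camera, 0 with an estimated correlation and 0 by fry for a direction. Without Adult replicate 2 the count was 2260 genes (1041 higher, 1219 lower). When Adult replicate 1 was left out it was 1, Eif2s3y, a Y-linked gene (-5.07), which was picked after its values had been seen. Of the 14 lists called, 2 were still called without Adult replicate 1, slow sarcomere and fatty acid oxidation. Under equal housekeeping means the calls of the embryonic sarcomere, imprinted growth, tendon cell, interferon response and glycolysis lists were lost. Equal array medians ended all of these but the interferon call (adjusted p = 0.0502 each), and cyclic loess ended those of the interferon response (0.115) and of glycolysis (0.521, median 0.011).

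A further question was whether the change with age repeats or opposes the change of the first week. Across the 12029 genes the log2 differences of P7 against P3 and of Aged against Adult, which share no array, correlated at r = -0.187, and 20 simulated draws of unchanged groups gave -0.089 to 0.061. The simulated genes were drawn independently of each other, while genes in the data are correlated. The simulated range here and the simulated value below therefore do not show what unchanged groups would give in these data. The observed correlation was 0.243 without Adult replicate 1. The differences of P7 against P3 and of Adult against P7 correlated at r = -0.072, and unchanged groups that share the P7 arrays in the same way gave -0.254 on average, while without Adult replicate 2 the value was 0.144. Housekeeping genes were not called in any comparison, and their median was -0.05 from P3 to P7, -0.13 from P7 to Adult, which turned positive in the 3 other scalings, -0.23 from P3 to Adult and 0.24 from Adult to Aged. Equal housekeeping means moved the median of all genes to 0.138 in Adult against P3 and to -0.147 in Aged against Adult. Housekeeping genes averaged 10.28 in Adult replicate 1, 10.75 in Adult replicate 2 and 10.66 to 10.80 in the other arrays. Their differences with Adult and the effect of this scaling therefore rest largely on Adult replicate 1.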

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

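A crossed pairing of Adult and Aged and a same-numbered pairing of P3 and P7 alone were chosen after the data had been seen. Leaving out 1 array at a time gave 0 to 22 genes for P7 against P3, 46 to 1892 for Adult against P7, 130 to 2858 for Adult against P3, 0 to 2260 for Aged against Adult and 183 to 3842 for the F test. Without an Adult array, whose replicates differed most, more genes passed, but for Aged against Adult 1 gene did without replicate 1 and 2260 without replicate 2. Leaving out an array of a compared group alters both the shared spread and that group's mean, and these were not separated. An array outside the comparison alters only the shared spread estimate, its prior and its degrees of freedom. Without either Aged array the median difference of all genes in Adult against P7 stayed at -0.071, yet fewer genes passed. That count therefore depended on the spread estimate to which the Aged arrays contribute, or on its prior or degrees of freedom, which were not separated. The correlation of P7 against P3 with Aged against Adult ran from -0.287 to 0.243, and that with Adult against P7 from -0.261 to 0.144. The labels state no pairing of the replicate numbers. Deviations of replicates from their group mean correlated at 0.385 between P3 and P7 but at -0.459 between Adult and Aged and under 0.1 in the other 4 pairs of groups, so the numbers were not taken to pair all arrays. A replicate block gave 0, 347, 620 and 0 genes and 563 for the F test, and the crossed pairing gave 0 for Aged against Adult. Pairing P3 and P7 by number in a fit of these 4 arrays, with 1 residual degree of freedom, gave 330 genes (283 higher, 47 lower), so the count of 0 for P7 against P3 did not hold under that pairing.

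With no filter on dim probe sets 1 gene passed for P7 against P3, Mir206 (named after its values were seen), and with array weights 1, Myh4. The stricter filter gave 267 genes for Adult against P7, with 6874 genes tested. Array weights gave 112 for Adult against P7, 138 for Adult against P3 and 2432 for the F test. Fits to the compared groups alone gave 49, 45 and 60 genes for the first 3 comparisons. For the array weights, the filters and these fits the cause was not tested. Array weights let the spread differ between arrays, while the main fit pools it over all groups. The main counts for Adult against P7 and Adult against P3 may therefore be too high for the wide spread of Adult. The other scalings, the mean of a gene's probe sets, the prior without trend, the robust prior and the fold threshold of 2 kept every total within 1.5 times. Equal housekeeping means moved the genes lower from 302 to 153 for Adult against P7 (137 higher) and from 406 to 240 for Adult against P3 (337 higher).

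In Aged against Adult the list medians with 1 array left out ran from -2.96 to 0.16 for fibroblast, -1.59 to 0.080 for basement membrane, -2.80 to 0.057 for smooth muscle, -3.27 to 0.48 for tendon cell and -1.17 to 0.21 for interferon response genes, each positive without Adult replicate 1. That of basement membrane genes in Adult against P3 ran from -1.36 to 0.11, positive without Adult replicate 2. The cause was not tested here. An estimated correlation ended 53 list calls and fry 33. For the embryonic sarcomere list in Adult against P7 the estimate was 0.0055, below the preset 0.01. Its unadjusted camera p still went from 3.42e-06 to 0.0092, so correlation between genes does not account for every lost call. None of the named genes that passed changed sign. Their 103 calls were each checked under up to 19 alternatives, and over these pairs of call and alternative 1628 were kept and 322 lost. Fits to the compared groups alone ended 61 of these calls and array weights ended 42. The losses given by gene above leave out these 2 alternatives. The robust prior and the fold threshold were not applied to lists.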

Other observations

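All tests in this part except the one on the brightness of X-linked genes were chosen after the result had been seen, and so were the genes singled out here.

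Genes on the X chromosome were frequent among those that fell from P7 to Adult. Of 356 tested X-linked genes 29 fell (8.15%), against 273 of 11673 other genes (2.34%), an odds ratio of 3.70 with a 95% interval of 2.40 to 5.54 (Fisher's exact test, two-sided, p = 2.28e-08). This test treats genes as independent, which they are not, so its p and interval do not measure the spread between animals. The X-linked genes that fell included the channel subunit Kcne1l, Atp1b4, Prr32 and Fndc3c1, and also Nrk (-4.56 ± 0.35), the calpain relative Capn6 (-4.44 ± 0.42), Maged2 (-4.32 ± 0.30) and the membrane protein Igsf1 (-3.61 ± 0.24), with n = 2 per group.

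Small nucleolar RNA genes, most of which guide the modification of other RNAs, were not a list fixed beforehand, and their enrichment was not tested. Of the 47 tested, 9 rose from P7 to Adult (median 0.88, 40 higher), where 129 of all 12029 genes rose, and 4 rose from P3 to Adult (median 0.29), while 0 passed from P3 to P7 (median -0.48, 40 lower) or from Adult to Aged (median -0.79, 42 lower). The Y-linked gene Eif2s3y had log2 intensities of 7.70 and 7.81 at P3, 7.94 and 7.04 at P7, 3.67 and 8.83 in Adult and 3.56 and 3.98 in Aged. The X-inactivation transcript Xist lay between 10.14 and 11.57 in all 8 arrays, so that 5 arrays held both transcripts, and whether animals were pooled stays open. Apart from the higher genes described next, Adult replicate 1 had the myogenic factor Myod1 at 9.26, against 12.63 or more in the other mature arrays.

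In Adult replicate 1, 1005 genes lay more than 1 log2 unit above each of the other 3 mature arrays and 708 lay as far below. RNA from connective tissue and vascular cells may have been in this preparation: 83.3% of 42 markers (35) of fibroblasts, tendon cells, endothelium and smooth muscle were among the higher genes, but these lists were pooled because they were high in this array, so the share tests nothing and the explanation stays open. Abundant transcripts of such cells were high too, with Col1a1 at 12.23 against 7.79 in Adult replicate 2 and Dcn at 13.63 against 10.51. The protocol's washing step, however, should remove these cells. In Adult replicate 2 as well, 38.1% of the markers were above the median of the tested genes on that array. The genes that were lower are another matter, since added cells dilute all fiber transcripts alike. Excitation-contraction coupling genes deviated by a median of -0.28 (SD 0.44, 17 genes) and the lower genes by -1.43. The lower genes were picked for lying more than 1 log2 unit below, so their lower median was fixed beforehand. The comparison therefore cannot decide whether dilution accounts for them. A pup sample under the wrong label was excluded, because its imprinted growth genes lay only 12.1% of the way from the other mature arrays to the pups.

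For the X-linked genes, brightness in the pups was tested with random gene sets matched on the level at P7, and none held as many fallen genes (at most 21, against 29, permutation p = 1e-04, the smallest they can give). Like the Fisher test, this p and the intervals below count genes and not animals. The sex of the animals was tested by leaving out either Adult array, since Adult replicate 1 alone of the 2 lacked Y-linked transcripts. The lowest odds ratio was 1.98 (95% interval 1.46 to 2.64), without Adult replicate 2, and it was 2.50 without Adult replicate 1, so neither explanation accounts for the pattern as a whole. A loss of X-linked fetal transcripts with maturation stays open as a candidate explanation that was not tested.

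Of 12 slow sarcomere genes 11 were higher in Aged than in Adult but 0 passed over all genes, and the list's call was lost with an estimated correlation (adjusted p = 0.513) and without Adult replicate 2 (adjusted p = 0.238). Other cells in Adult replicate 1 were excluded as the only cause, since against Adult replicate 2 alone the median was 1.41 (SD 0.64, 11 of 12 higher). Sex could not be told apart from age, because Adult replicate 1 was the only Adult array that lacked Y-linked transcripts like the Aged arrays. Against Adult replicate 1 alone the median was 0.77 with an SD of 0.99 between members (8 of 12 higher). Both SDs measure the spread between genes, not between animals. A larger share of slow fibers among those collected may also contribute, since the mean of the list differed by 0.78 between the 2 Aged arrays, against 0.93 between the ages, while the fast sarcomere mean differed by 0.12 between the Aged arrays. Age itself stays among the open explanations and was not tested apart from these.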
